A study of Rattus norvegicus with 6 samples.

How the data were processed

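Gene expression was measured by RNA sequencing in 6 libraries of neonatal rat ventricular cardiac fibroblasts, 3 from cells on fibronectin-coated glass (UT) and 3 from cells on fibronectin with transthyretin fibrils (TTR). RNA was taken after 48 h on the substrate. The authors deposited a single table of raw counts per gene, in whole numbers and without normalization. The submitters' processing notes name STAR, featureCounts, edgeR and the rat build rn6, with no versions. The annotation, the strand setting, the treatment of multi-mapping reads and the sequencing mode are not given in the sources used here. Reads shared between near-identical gene copies, or between overlapping or antisense genes, may therefore be split or lost in ways that the counts do not show.

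The table holds 27108 rows, each an Ensembl rat gene ID, and all rows name a gene. Of these, 18627 had a count in at least 1 library. The table gives no symbols, and the reference table used here pairs 0 of the 27108 IDs with a symbol, so genes are given by ID. The 29 gene lists fixed before the data were examined, with 707 symbols for inflammatory, matrix, contractile and stress programmes, for markers of other heart cell types and for mitochondrial transcripts, were therefore not analysed here. The same holds for the tests of those lists, for the rule that would have named genes from them or by symbol, and for the transcript of transthyretin itself. In place of that rule, the 2 genes with the smallest p in each direction are named. They were chosen after their values were seen.

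Total counts ran from 6574199 to 11774729 per library. All columns of the table were matched to samples by their description labels. All pairs of libraries were compared by a chi-square test of their counts over genes with a mean count of at least 20. The smallest ratio of chi-square to degrees of freedom was 8.78 within a group and 5.51 between groups, for UT replicate 3 and TTR replicate 1, so no pair agreed within sampling noise. Nothing in the labels says that the replicates came from separate cell isolations. The p-values measure the spread between these samples, which may be technical.

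The main test was the edgeR (version 4.0.16, R 4.3.3) quasi-likelihood F-test of TTR against UT on all 6 libraries, two-sided, with group as the only term. Low genes were removed with filterByExpr at its default minimum count of 10, which left 12049 genes, and libraries were scaled by TMM factors. Genes past a Benjamini-Hochberg adjusted p of 0.05 over the tested genes were called. Log2 folds are TTR minus UT, and their standard errors (SE) were obtained from the fold and the F statistic. CPM values, counts scaled to the TMM-adjusted library size, were computed here. Principal components were taken over log2 CPM of the 12049 genes with a prior count of 2. Measures of single libraries were compared by an exact permutation test, two-sided, which cannot go below p = 0.1 with 3 against 3 libraries.

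Alternatives fixed before the data were examined were RLE or upper quartile factors, library totals alone, DESeq2 (1.42.0), limma-voom (limma 3.58.1), no low count filter, a filter of 1 CPM in at least 3 libraries, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were the edgeR likelihood ratio test, robust dispersion estimates, 1 or 2 surrogate variables from sva (3.50.0), and thinning of all libraries to the smallest total. Adjusted p-values that DESeq2 left undefined stayed undefined.

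The tests were tried on simulated data for the TTR against UT comparison, with 200 genes changed, 100 of them 2-fold and 100 of them 4-fold. Counts were drawn once for the 12049 genes from the real means, dispersions and library sizes. The libraries were drawn independently, without any variation shared between them. The edgeR quasi-likelihood test recovered 69% of genes changed 2-fold and 97% of genes changed 4-fold, with 19 false calls. DESeq2 recovered 72% and 96% with 34 false calls. The likelihood ratio test recovered 77% and 98% with 43 false calls. For limma-voom the values were 69% and 96% with 17 false calls. With 2 surrogate variables the edgeR quasi-likelihood test recovered 11% and 73% with 8 false calls.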

Results

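Cardiac fibroblasts, the matrix-producing cells of the heart wall, were isolated from the ventricles of neonatal rats and cultured on glass coated with fibronectin alone (UT) or with fibronectin and fibrils of transthyretin (TTR). Transthyretin is a plasma carrier protein whose fibrils accumulate in the heart in transthyretin amyloidosis. Each group held 3 libraries, sequenced after 48 h on the substrate. The series asks how contact with the fibrils alters gene expression in these cells. The UT libraries held 7262313, 6906639 and 6897626 counts, and the TTR libraries held 11774729, 7287706 and 6574199. Between 15476 and 16237 genes had at least 1 count in a library.

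The most variable part of the expression profiles did not follow the substrate. The first component held 39.6% of the variance and placed UT replicate 3 and TTR replicate 1 together at scores of 23.0 and 25.5, with UT replicate 1 and TTR replicate 3 at the other end at -18.5 and -30.2. The second component, with 23.6% of the variance, set UT replicate 2 and TTR replicate 2 apart from the other 4 libraries. Only the third of these components, with 18.8%, separated the groups, with UT libraries between 7.55 and 21.5 and TTR libraries between -14.1 and -12.1. The exact permutation test gave p = 0.1 for the third component, the smallest that 3 against 3 libraries allow, and p = 1 for the first (adjusted p = 0.6 and 1 over 6 library measures).

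**Figure D1:**
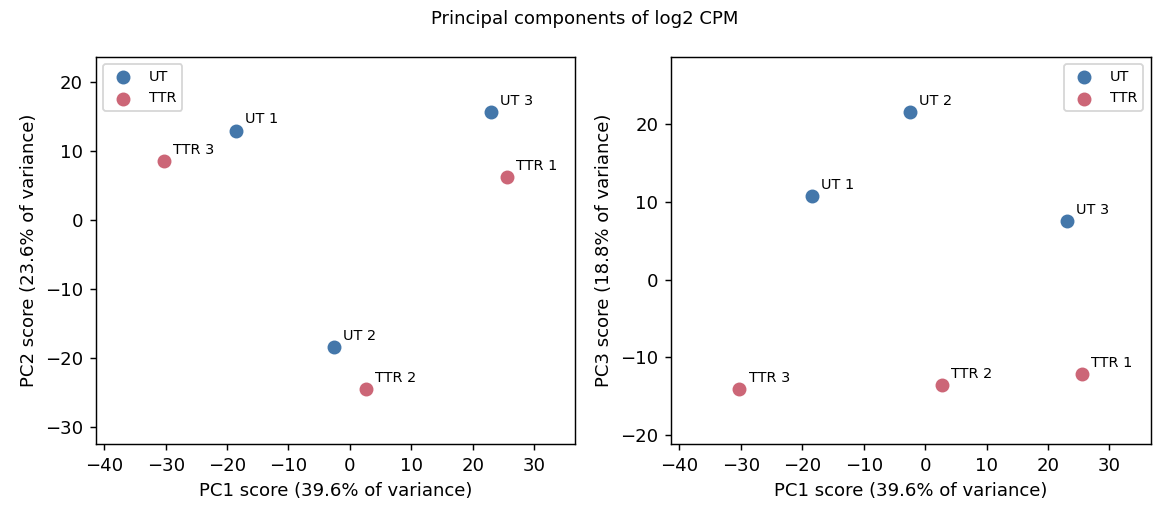
Scores of the 6 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM over 12049 genes, with the share of variance on each axis; each point is a library. The groups separate on component 3, where TTR libraries lie between -14.1 and -12.1, and overlap on components 1 and 2.

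The make-up of the libraries was compared by 3 measures, with a test that could not have passed 0.05 at this size. The 10 most abundant genes took 8.50% ± 0.165 of the counts in UT and 8.61% ± 0.168 in TTR (SD, n = 3, exact permutation p = 0.6). The number of genes detected was 15626 ± 166 in UT and 15915 ± 291 in TTR (SD, n = 3, exact permutation p = 0.2), without adjustment for the greater depth of TTR replicate 1. For total counts the exact permutation p was 0.6.

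Between the groups, 1 gene passed the threshold of the main test as higher on TTR, and no gene passed it as lower. The next smallest adjusted p in this edgeR test was 0.0565, for a gene higher on TTR. The smallest for a gene lower on TTR was 0.0689, so the count depends closely on the threshold. Leaving out 1 library moved the count of calls to 9 without TTR replicate 1 and to 2 without UT replicate 2, all of them higher on TTR. It stayed at 1 for each of the other 4. The gene called in the main test, ENSRNOG00000000239, was 6.16-fold higher on TTR, at 10.4 ± 2.94 CPM on UT and 64.3 ± 1.39 CPM on TTR (SD, n = 3). Its log2 difference was 2.62 (SE 0.19), with an adjusted p of 0.00248 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Its counts were 100, 54 and 66 in the UT libraries and 765, 466 and 422 in the TTR libraries. ENSRNOG00000000239 also passed the threshold with DESeq2, with limma-voom and with each library left out in turn, and did not pass with the replicate number as a block (adjusted p = 0.107).

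DESeq2, which was fixed beforehand as an alternative, called 37 genes on the same counts, 35 higher and 2 lower on TTR. The 35 higher genes had a median log2 change of 2.42, with the smallest at 0.72. The largest among genes with more than 3 counts over the UT libraries was 4.71. The folds of 2 genes with 0 counts in all UT libraries, and of 4 with 1 to 3 counts, rest on a near-empty baseline, and setting the first 2 to a floor of 3 counts over the UT group left the median at 2.42. Of the 35, 26 were at least 2-fold higher and 14 at least 8-fold higher, and 13 lay under 1 CPM on UT. Their median level was 3.96 CPM on UT and 13.2 CPM on TTR. The main test included 32 of the 35, and in all 32 every TTR library lay above every UT library, with an unadjusted edgeR p of at most 0.00294. The 2 lower genes likewise had no overlap between the groups. As these genes were selected on the same counts, this is no separate evidence for them. The main call was among the 37. In the simulation DESeq2 made 34 false calls against 19 for edgeR, so its list may hold more errors. That simulation drew each library independently, whereas the real libraries also varied along lines other than the substrate. It also held only the 12049 genes of the main test, whereas DESeq2 on the real counts tested 18627. The simulation therefore cannot say how many of the 37 calls are false.

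The 2 genes with the smallest p in each direction were picked as extremes, so the size of their shifts is not typical. Over all tested genes the median size of the log2 change was 0.10. Besides ENSRNOG00000000239, ENSRNOG00000002802 stood at 4.20 ± 1.44 CPM on UT and 40.0 ± 16.6 CPM on TTR (SD, n = 3), a log2 difference of 3.23 (SE 0.38) with an adjusted p of 0.0565 by edgeR and 1.32e-16 by DESeq2. Among genes with lower levels on TTR, ENSRNOG00000018454 stood at 47.3 ± 15.9 CPM on UT and 10.5 ± 3.54 CPM on TTR, a log2 difference of -2.19 (SE 0.30) with an adjusted p of 0.0689 by edgeR and 1.85e-10 by DESeq2. ENSRNOG00000018434 stood at 10.0 ± 2.68 CPM on UT and 3.04 ± 1.33 CPM on TTR, a log2 difference of -1.76 (SE 0.35) with an adjusted p of 0.315 by edgeR and 0.00409 by DESeq2. These 3 genes therefore passed in DESeq2 and missed the threshold in the main test.

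**Figure D2:**
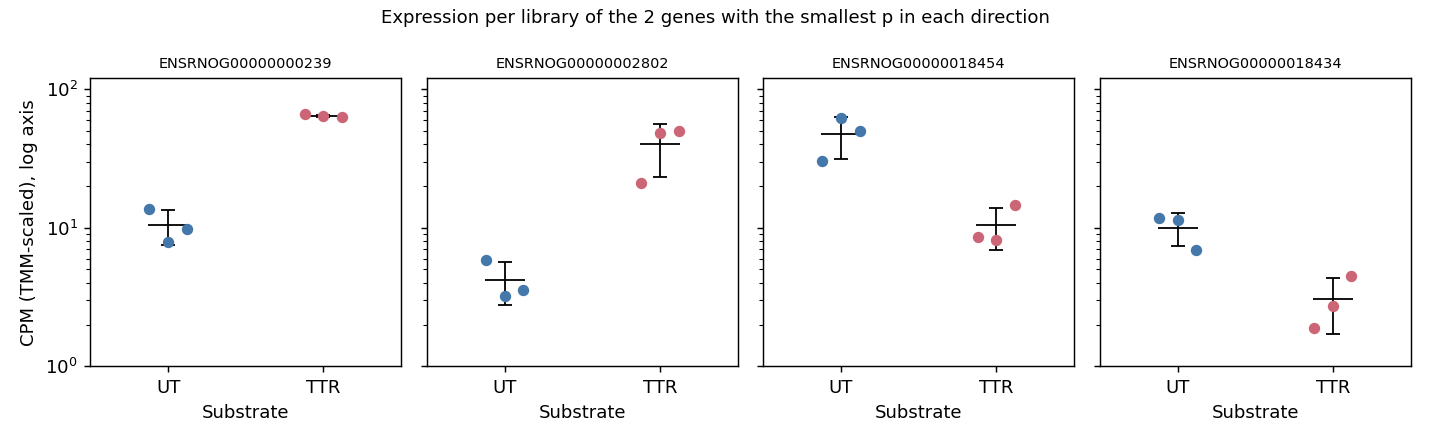
CPM per library on a log axis for the 2 genes with the smallest p in each direction, with UT in blue and TTR in red; points are libraries, and bars give the mean and SD of 3. For each gene, all TTR libraries lie on one side of all UT libraries.

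Genes with the smallest p were mostly higher on TTR. Of the 25 tested genes with the smallest edgeR p, 24 were higher on TTR and 1 was lower. Of the first 100, 75 were higher and 25 lower. A split that did not follow the substrate set UT replicates 1 and 2 with TTR replicate 3 against the rest. It gave 84 of its first 100 genes in one direction, and 23 of its first 25. This split follows the first principal component and leaned furthest of the 9 other splits, the next reaching 64 and 18. At an unadjusted p under 0.05, 285 genes were found, 182 higher and 103 lower. The balance at this threshold rested on TTR replicate 3, without which 258 were higher and 266 lower, and it turned with 1 surrogate variable (286 higher and 298 lower) and with 2 (509 higher and 623 lower). Independent tests of exchangeable libraries would give 602 such genes. Without overlap between the groups, 452 genes (3.75%) were higher and 373 (3.10%) lower in all TTR libraries, where exchangeable libraries would give 5% in each direction. Neither value is the chance level for these libraries, which also differ along lines other than the substrate. Over the 9 other splits the count of genes at an unadjusted p under 0.05 ran from 35 to 1555. The count was 105, 35 and 142 in the splits that, like the real one, part each cross-group pair described below. Those pairs were found in the same counts, so this is no separate evidence.

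**Figure D3:**
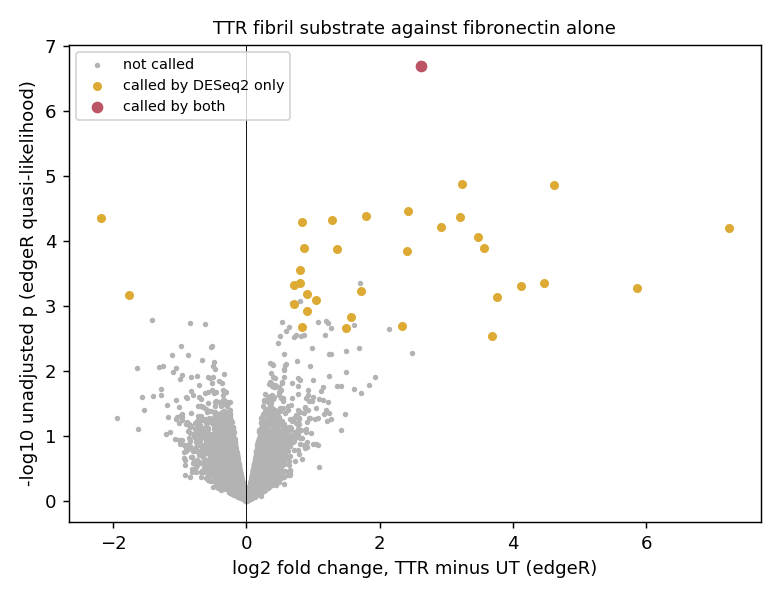
Log2 fold change of TTR against UT (x axis) and -log10 of the unadjusted edgeR p (y axis) for the 12049 tested genes; each point is a gene. ENSRNOG00000000239, called by both tests, is in red at 2.62; genes called by DESeq2 alone are in yellow and mostly on the right.

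For most genes the spread among the libraries was small enough to bound the difference between these 2 groups. As this spread may be technical, the intervals do not bound the effect of the fibrils on the cells. The median size of the log2 change was 0.10 over all tested genes, with a median SE of 0.17. Of the 6698 genes between 10 and 100 CPM, 97.3% had a 95% interval that lay within a 2-fold change in either direction, as did 99.2% of the 2156 genes over 100 CPM. Among the 3195 genes between 1 and 10 CPM the share was 55.3%, so a 2-fold change lay outside the interval for fewer of these low genes.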

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

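RLE factors, upper quartile factors, library totals alone, limma-voom and robust dispersion estimates all left 1 call, ENSRNOG00000000239, which was called under every setting run except the replicate block. DESeq2 gave 37 calls (28 at least 2-fold), no low count filter gave 36 (30 at least 2-fold), and a filter of 1 CPM in at least 3 libraries gave 3, all at least 2-fold. Without the filter, edgeR's prior degrees of freedom rose from 5.08 to 17.5, and 34 of its 36 calls were also DESeq2 calls. Chosen after seeing the data were the likelihood ratio test with 44 calls (32 at least 2-fold), 1 surrogate variable with 27 (19 at least 2-fold), 2 surrogate variables with 155 (49 at least 2-fold) and thinning to the smallest total with 2 (2 at least 2-fold). Leaving out 1 library gave between 1 and 9 calls, and between 1 and 9 of at least 2-fold. The 9 came without TTR replicate 1, all of them DESeq2 calls, and 2 came without UT replicate 2. The cause was not tested.

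With the replicate number as a block, edgeR gave 0 calls (0 at least 2-fold), with 223 genes at an unadjusted p under 0.05. In expression, the numbers did not mark the libraries that deviated most alike, except for number 2. The labels do not say whether a shared number marks a shared day or cell isolation. Deviations from the group means correlated at -0.38 for number 1, 0.44 for number 2 and -0.40 for number 3, and only the libraries numbered 2 correlated best with their own number. ENSRNOG00000002802 passed under 7 of 19 settings (adjusted p from 1.32e-16 to 0.483), ENSRNOG00000018454 under 5 (1.85e-10 to 0.404) and ENSRNOG00000018434 under 5 (0.000165 to 1). All 4 named genes kept their direction in all 19, which could hardly be otherwise for genes whose groups do not overlap. The planned tests of gene lists and list members, and the cell type summaries, were not run because no row carries a symbol. Genes of 1 to 10 CPM had the widest intervals, and depth was not separated from spread.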

Other observations

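The counts over other splits by edgeR and the tests of cells of another type and of scaling were chosen after the result they measure was seen. The surrogate variable and thinning tests were added after the main results were seen. The test of scaling took the place of one set beforehand, and its bound was changed once more after its counts were seen; the reading of the surrogate variable test was made stricter after its counts were seen.

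The lean toward genes higher on TTR fibrils held among the genes with the smallest p, at 22 to 24 of the first 25 under all 19 alternative settings. Those settings refit the same libraries, so this is no separate evidence for the lean. At an unadjusted p under 0.05 the lean did not hold, being gone without TTR replicate 3 and with surrogate variables. The greater depth of TTR replicate 1 is argued against, since DESeq2 still called at least 30 genes higher and at most 3 lower in 10 draws with all libraries thinned to the smallest total. The choice among the 4 scalings did not produce the lean, as 23 or 24 of the first 25 genes were higher under each. An error of scaling that all 4 share stays open: the test set beforehand was met against it, with the median log2 fold moving by at most 0.0057 where the smallest DESeq2 call was 0.72, but all 4 leave the median gene near no change, so that test could hardly have come out otherwise. In its place, 65 tested genes lay over 2-fold above the median gene and 28 over 2-fold below it. The prediction for a shared error was equal numbers. The counts were 89 and 89 without UT replicate 3, 62 and 65 without TTR replicate 2, and 70 and 137 without TTR replicate 3. Counting from the median gene takes out any shift common to all genes, so these counts cannot test such an error either. The grouping of the libraries stays open: 2 of the 10 splits leaned as far, the real one with 75 of its first 100 included, and the highest other reached 84. Among the first 25 genes the real split had 24 and the highest other 23. The other splits that part each cross-group pair described below leaned less, at 60, 51 and 51 of their first 100. Among their first 25 they stood at 15, 15 and 14. Those pairs were found in the same counts, and 10 splits are too few for a share under 0.05. Cells of another type in the TTR cultures cannot be told apart from a response of the fibroblasts, because 0 marker symbols were matched to rows. A response to the fibrils, the factor the design names, stays open as a hypothesis beside these.

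Libraries of different groups deviated together, though not by number. Deviations from the group means correlated at 0.58 between UT replicate 3 and TTR replicate 1, 0.52 between UT replicate 1 and TTR replicate 3 and 0.44 between UT replicate 2 and TTR replicate 2, and at -0.09 or below for the other 6 combinations. Depth of the libraries did not account for this, since all 3 UT libraries kept their closest TTR library in each of 10 thinned draws. A factor shared across the groups, such as a day or a cell isolation that the labels do not record, is a candidate explanation that stays open. With 2 surrogate variables edgeR called 155 genes for the real split, against 1 without them and at most 101 for any other split, which is the result set beforehand as favouring such a factor. That prediction was met, but its reading was made stricter after the counts were seen, because the same step also raised other splits. The test is left undecided here. The step took UT replicates 1 and 3 with TTR replicate 3 from 0 calls to 101. With TTR replicate 1 in place of TTR replicate 3 the rise was from 0 to 91. A rise is therefore not particular to the substrate, though each of these splits keeps a correlated pair on one side. The remaining splits stood between 0 and 71 calls with surrogate variables, at 0 for those that part each of the 3 correlated pairs. A shared factor could raise other splits too, so these rises do not argue against it. Surrogate variables are estimated from the same counts, and the 155 calls, of which 34 were DESeq2 calls, are not independent evidence of a longer list.

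The 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 1 call by edgeR, and 2 of the 10 splits, the real one included, gave as many, the highest other being 18. For calls of at least 2-fold, 2 of the 10 splits gave as many as the real 1, the highest other being 15. By DESeq2 the real split gave 37 calls, and 4 of the 10 splits gave as many, the highest other being 163. Some splits, like the real one, part every pair that deviated together. They set UT replicates 1 and 2 with TTR replicate 1, or UT replicates 1 and 3 with TTR replicate 2. A further such split set UT replicate 1 with TTR replicates 1 and 2. These splits gave 0 calls by edgeR and by DESeq2. The pairs were found in the same counts, so this does not settle the question. The split with the highest counts in both tools set UT replicates 1 and 2 and TTR replicate 3 against UT replicate 3 and TTR replicates 1 and 2. It follows the first principal component, and it points to a structure of the samples other than the substrate.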
